A study of Mus musculus with 12 samples.

How the data were processed

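H4K12ac was measured by ChIP-seq in neuronal and non-neuronal nuclei of C57B/6JRj wild-type mice, with an input for each ChIP library, 12 libraries in all. Per the labels, vehicle was 18 g/L cyclodextrin in water and SAHA was given at 0.67 g/L, by mouth for 4 weeks. Per the labels' protocols, fixed nuclei were sonicated to fragments of about 300 bp, and 0.5 µg of antibody was used with 500 ng of chromatin. Groups were taken from the source names and each ChIP library was paired with its input through the titles. Whether nuclei of several animals were pooled is not given in the sources used here.

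Per the submitters' processing notes, CASAVA 1.8.2 and Bowtie2 were used and the genome build was mm10. The deposited values are a signal, normalized by the authors per the file headers, with 1 mean value at each of 4001 positions from -2000 to 2001 relative to the TSS (position 0 is absent). The scaling factor, the set of TSS, how they were averaged and how duplicate reads were treated are not given in the sources used here. Input was deposited in files of its own. A profile averaged over many TSS cannot show which genes changed, and an average can move through few strong genes or many weak ones. Libraries are comparable only as far as the authors' normalization makes them so.

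Signal was read as deposited and multiplied by 1000 for printing. Differences between neighbouring positions were whole multiples of 1 step per library (tolerance 0.1 of a step) at 100% of positions. The step was taken as 1 read. The differences had their most negative autocorrelation, -0.522 to -0.486, at a lag of 300 bp in every library, so reads were taken as counted over 300 bp. The inverse of the step was 36400000 to 78000000. It equals the number of reads only if summed coverage was divided by that number, which is an inference. Over-dispersion of the steps was 1.57 to 1.72. The counting error of the mean within 500 bp, from the step, the 300 bp and the over-dispersion, was 0.0798% to 0.158%. It is a lower limit, since nearby TSS can share reads, and 95% counting intervals of differences rest on it. The recovery of step, read length and window ratio (within a log2 of 0.01) was tested on simulated data and succeeded in 3 of 3 simulated cases. The simulated reads had over-dispersion near 1, unlike the data, and only the length of 300 bp. The simulation therefore does not test the counting intervals or other lengths.

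The main value, fixed before the data were examined, was the mean over positions within 500 bp of the TSS of ChIP divided by its own input, and differences were log2 ratios of this value. The flank was the outermost 10% of positions on each side, 400 positions each. ChIP was compared with input by an exact two-sided sign-flip permutation test over 6 pairs, and the populations by the same test over 3 pairs, which cannot go below p = 0.25. No test was made for age or SAHA, with 1 library per group. The features named were fixed beforehand as the maximum upstream, the minimum within 200 bp, the maximum downstream and the means at 1000 bp on either side. The upstream maximum was sought more than 200 bp upstream. Regions of 500 bp, 8 in all, and single positions were added after the data were examined. The upstream dip, the peak width and the ratio of the rise upstream to that downstream were not among the features fixed beforehand. Gene lists and cell type markers had also been fixed, but the profiles hold no genes, so they were not used.

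Alternatives fixed beforehand were ChIP alone, input subtracted, windows of 1000 and 200 bp, division of each library by its own flank, and leaving out each pair in turn. A pseudocount applies to tables of genes and was not used. Added after the data were examined were 1 common input (the mean of the 6 inputs), the exchange of the 2 aged vehicle inputs between the populations, and the share of the age difference covered by the SAHA difference. The value of this share with no effect was simulated with 100000 draws of 3 libraries from 1 normal distribution. The groups and pairs given by the labels were kept in all main values. Calculations used Python 3.11.15, NumPy 2.4.6 and Matplotlib 3.10.9.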

Results

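Acetylation of histone H4 at lysine 12 (H4K12ac), a mark found at the promoters of active genes, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse brain nuclei. The file headers name CA1, a subfield of the hippocampus. Nuclei came as a neuronal and a non-neuronal population from wild-type mice in 3 conditions. These were mice of 3 months given vehicle, mice of 20 months given vehicle, and mice of 20 months given SAHA (vorinostat), an inhibitor of histone deacetylases. Each of the 6 groups had 1 ChIP library and 1 input library, the input being sonicated chromatin sequenced without immunoprecipitation. With 1 library per group, no age or SAHA difference has a replicate error or a test, and all values below describe these 12 libraries. Animals of another genotype, named in the series, were not analysed here. Each library was a mean signal profile over about 2000 bp on either side of the transcription start site (TSS), so no single gene could be read from it. Signal is given as the deposited value multiplied by 1000. The smallest unit of signal gave divisors of 36400000 to 65700000 in the ChIP libraries and 42200000 to 78000000 in the inputs. The lowest ChIP divisor was that of the young neuronal library and the highest that of the aged vehicle neuronal library. The neuronal age comparison therefore also sets the lowest against the highest divisor. The counting error of a mean within 500 bp of the TSS was 0.0798% to 0.158%. It covers counting error only, not variation between animals or preparations.

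The first comparison asked where H4K12ac lay relative to the TSS and how far it rose above input. H4K12ac peaked just downstream of the TSS in all 6 ChIP libraries, with maxima between 222 and 240 bp. The maximum was 14.7 in neuronal nuclei at 3 months, 12.3 at 20 months with vehicle and 14.3 with SAHA. In non-neuronal nuclei it was 16.2, 14.5 and 15.5 in the same order. Within 500 bp of the TSS, the ChIP signal was 2.23 to 3.01 times that of its own input. The mean log2 ratio was 1.46 ± 0.16 (SD, n = 6 pairs), above 0 in 6 of 6 pairs (exact two-sided sign-flip permutation test, p = 0.03125, the smallest possible with 6 pairs). In the outermost 10% of positions on each side, called the flank here, the ratio was still 1.25 to 1.43, with a mean log2 ratio of 0.42 ± 0.097 (SD, n = 6 pairs, exact permutation p = 0.03125). The test asks only whether ChIP exceeded input over these 6 pairs, which come from 6 different groups.

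**Figure D1:**
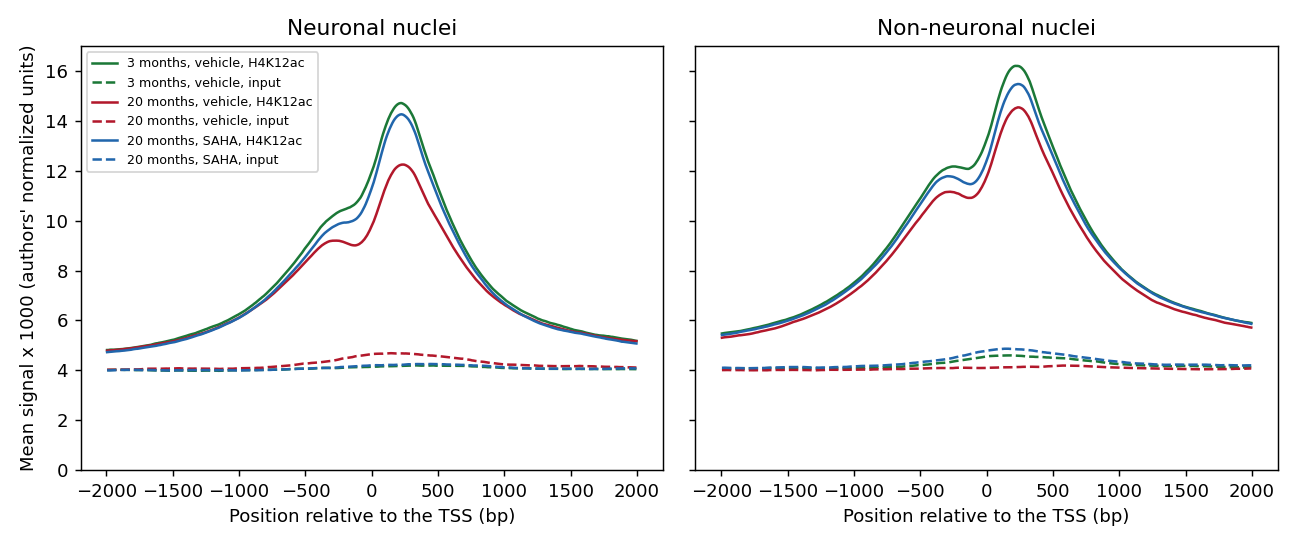
Mean H4K12ac signal (deposited value times 1000) against position relative to the TSS in bp, for neuronal and non-neuronal nuclei, 1 solid line per ChIP library and 1 dashed line per input. The ChIP maxima lie 222 to 240 bp downstream of the TSS, and the aged vehicle line is the lowest of the ChIP lines near the TSS in both populations.

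Upstream of the TSS the ChIP profiles differed in shape. Non-neuronal libraries had an upstream maximum at -252, -271 and -294 bp at 3 months, 20 months with vehicle and 20 months with SAHA. The signal between that maximum and the TSS dipped by 0.861%, 2.26% and 2.77% below it, against 3 counting errors of 0.831%, 0.870% and 0.796%. These counting errors are for means over 200 bp, whereas each dip lies between single positions picked as extremes, so they are a scale only. The young non-neuronal dip barely exceeded its own and does not establish a separate maximum. In neuronal nuclei the aged vehicle library had an upstream maximum at -270 bp with a dip of 2.12%, against 3 counting errors of 0.843%. The young neuronal library had no separate upstream maximum, and the dip in the aged SAHA neuronal library was 0.0639%, within 3 counting errors of 0.920%.

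The inputs were nearly flat at distance from the TSS but not near it. Their flank signal lay between 4.03 and 4.15. Within 500 bp of the TSS, 3 inputs stood well above their flank, by 11.2% in aged vehicle neuronal nuclei, 8.68% in young non-neuronal nuclei and 12.4% in aged SAHA non-neuronal nuclei. The young and aged SAHA neuronal inputs were 2.71% and 3.44% above their flank, and the aged vehicle non-neuronal input 2.00%. The 15 pairs of inputs differed by a log2 of 0.00999 to 0.18 in this window, with a median of 0.11. These pairs share 6 libraries and hold no variation from immunoprecipitation. Counts of pairs below are therefore a scale only, not a measure of spread between ChIP libraries. Since the inputs with a rise differed between conditions, each ChIP difference below is given both divided by its own input and for the ChIP libraries alone.

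**Figure D2:**
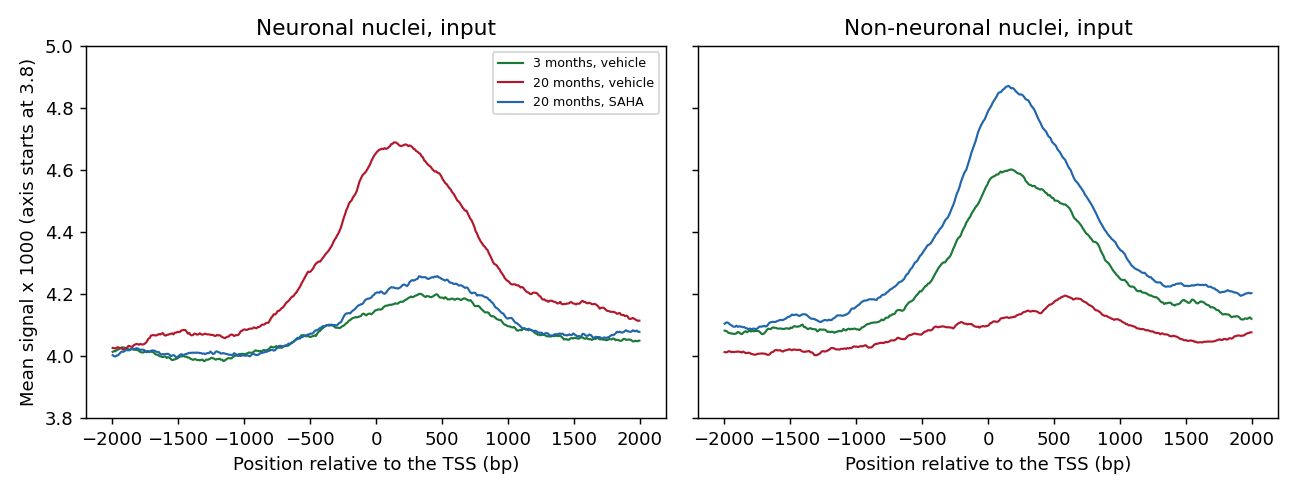
Input signal (deposited value times 1000, axis not starting at 0) against position relative to the TSS in bp, 1 line per library. The aged vehicle neuronal, young non-neuronal and aged SAHA non-neuronal inputs rise 8.68% to 12.4% above their flank near the TSS, and the others 2.00% to 3.44%.

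The age comparison set vehicle-treated mice of 20 months against those of 3 months. In neuronal nuclei the aged library had less H4K12ac around the TSS. Within 500 bp the ChIP signal was 11.9 at 3 months and 10.2 at 20 months, a difference of -14.3% (log2 -0.22, 95% counting interval -0.23 to -0.22). Divided by own input, the fold over input was 2.86 and 2.23 and the log2 difference -0.36 (95% counting interval -0.37 to -0.35). The difference was -16.0% from 1 to 500 bp downstream, -12.0% in the 500 bp upstream, and -0.459% from 2000 to 1501 bp upstream. It was greatest at position 3, at -18.2%. The neuronal inputs differed the other way, by a log2 of 0.13. The ChIP difference exceeded that of all 15 pairs of inputs, which are a scale only.

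In non-neuronal nuclei the aged vehicle library also had less ChIP signal. Within 500 bp of the TSS it was 13.5 at 3 months and 12.2 at 20 months, a difference of -9.52% (log2 -0.14, 95% counting interval -0.15 to -0.14). It was -10.1% from 1 to 500 bp downstream and -8.79% in the 500 bp upstream, and still -3.41% from 2000 to 1501 bp upstream. Divided by own input, the fold was 3.01 and 2.97 and the log2 difference -0.023 (95% counting interval -0.030 to -0.017). The non-neuronal inputs differed by a log2 of -0.12 in the same window. The ChIP difference exceeded that of 11 of the 15 pairs of inputs.

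The age difference was further from 0 in neuronal than in non-neuronal nuclei, by a log2 of -0.34 divided by own input and -0.078 for the ChIP libraries alone. The same contrast of the inputs themselves was 0.25, so the larger value rests mainly on the inputs. With the 2 aged vehicle inputs exchanged it was -0.041. With 1 library per group this difference was not tested.

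**Figure D3:**
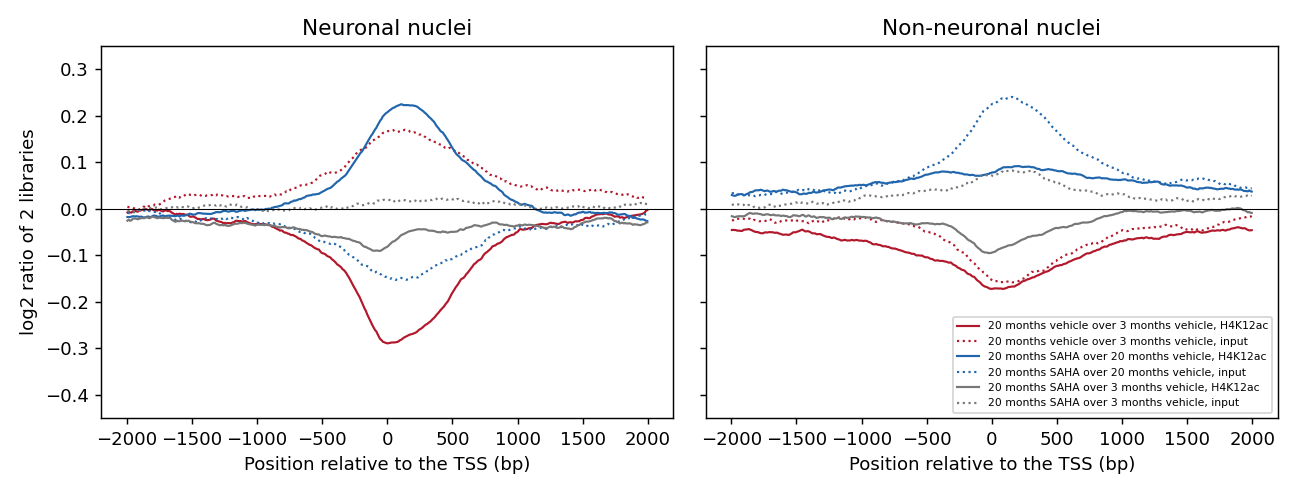
Log2 ratio of ChIP signal (solid) and of input signal (dotted) against position relative to the TSS in bp, for aged over young vehicle, aged SAHA over aged vehicle and aged SAHA over young vehicle, in each population. The ChIP age ratio is lowest at position 3 in neuronal nuclei (-18.2%) and at 87 in non-neuronal nuclei (-11.3%), and the ChIP ratio of SAHA over aged vehicle is highest at 109 (16.9%) and 203 (6.62%).

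The SAHA comparison set mice of 20 months given SAHA for 4 weeks against mice of that age given vehicle. In neuronal nuclei the SAHA library had more H4K12ac around the TSS. The ChIP signal within 500 bp was 11.4 with SAHA and 10.2 with vehicle, a difference of 11.8% (log2 0.16, 95% counting interval 0.158 to 0.165). Divided by own input, the fold was 2.72 and 2.23 and the log2 difference 0.28 (95% counting interval 0.28 to 0.29). It was 14.9% from 1 to 500 bp downstream and 8.03% in the 500 bp upstream. From 2000 to 1501 bp upstream it was -1.08%, so the difference lay near the TSS. The neuronal inputs differed by a log2 of -0.12, and 13 of the 15 pairs of inputs differed by less than the ChIP libraries.

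In non-neuronal nuclei the direction of the SAHA difference depended on the input. The ChIP signal within 500 bp was 12.9 with SAHA and 12.2 with vehicle, a difference of 5.85% (log2 0.082, 95% counting interval 0.079 to 0.085). The ChIP signal was higher with SAHA at 100% of positions, by 6.22% from 1 to 500 bp downstream and 2.54% from 2000 to 1501 bp upstream. Divided by own input, the fold was 2.76 with SAHA and 2.97 with vehicle, a log2 difference of -0.10 (95% counting interval -0.11 to -0.097). The inputs differed by a log2 of 0.18, more than the ChIP libraries did. Of the 15 pairs of inputs, 6 differed by less than the ChIP libraries.

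The aged SAHA libraries were then set against the young vehicle libraries. In neuronal nuclei the ChIP signal was -4.16% from the young value (log2 -0.061, and -0.075 divided by own input). In non-neuronal nuclei it was -4.23% (log2 -0.062, and -0.13 divided by own input). In each population, 5 of the 15 pairs of inputs differed by less than these ChIP libraries. Expressed as a share of the age difference in ChIP signal, the SAHA difference was 70.9% in neuronal and 55.6% in non-neuronal nuclei. This share was defined after the data were examined, and both of its differences use the aged vehicle library. In simulated libraries that varied alike with no effect, the median share was 50.5%, and 42.6% and 48.2% of draws gave a share as large as the neuronal and the non-neuronal one. In non-neuronal nuclei it was -420% when divided by own input, since the SAHA difference then had the opposite sign.

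**Figure D4:**
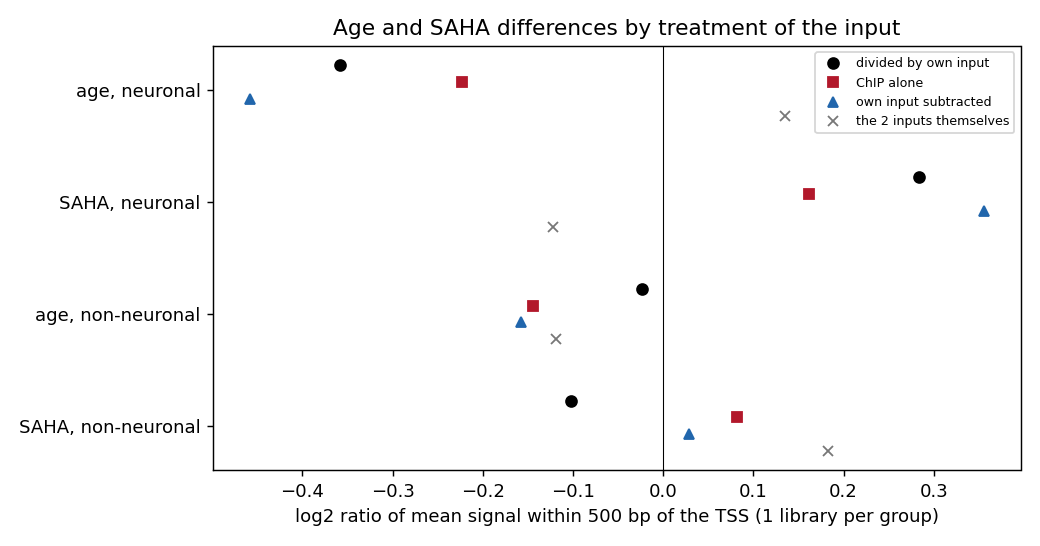
Log2 ratio of mean signal within 500 bp of the TSS for age and SAHA in each population, divided by own input (circles), for ChIP alone (squares), with own input subtracted (triangles) and for the inputs themselves (crosses), 1 library per group and no replicate error. The non-neuronal SAHA difference is -0.10 divided by own input and 0.082 for ChIP alone.

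The populations were compared within each condition. Neuronal nuclei had less H4K12ac signal within 500 bp of the TSS than non-neuronal nuclei in all 3 conditions. For ChIP alone the log2 difference was -0.18 at 3 months, -0.26 at 20 months with vehicle and -0.18 with SAHA. Divided by own input it was -0.074, -0.41 and -0.023, with a mean of -0.17 ± 0.21 (SD, n = 3 pairs, exact two-sided sign-flip permutation p = 0.25, the smallest possible with 3 pairs). Without the aged vehicle pair the mean was -0.049. The ChIP flanks differed by nearly as much, with a mean log2 of -0.19 ± 0.028 (SD, n = 3 pairs, exact permutation p = 0.25). The ChIP signal over its own flank was lower in neuronal nuclei in 1 of 3 conditions, with a mean log2 of -0.020 ± 0.073 (SD, n = 3 pairs, exact permutation p = 1). With ChIP and input each divided by its own flank, the mean was 0.0055.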

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

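The tests of explanations in this part were all chosen after the profiles had been seen, as were the bounds they use and the common input, and the tests of background and admixture in the aged neuronal library were revised after their first results.

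After division by own input, the SAHA difference within 500 bp of the TSS was above 0 in neuronal nuclei (log2 0.28) and below 0 in non-neuronal nuclei (-0.10), so the populations went opposite ways, by 0.39, a difference that was not tested, with 1 library per group. With 1 common input, which all but cancels and so nearly repeats ChIP alone, the non-neuronal difference was 0.082. The opposite sign therefore rests on the inputs. A smaller share of evenly spread background reads in the non-neuronal SAHA ChIP library may account for its higher signal. Its profile followed the aged vehicle profile along a straight line with residuals of -0.653% to 0.649%, with a fixed point at 4.05 (3.63 to 4.58 for a 1% change of scale) against input flanks of 4.03 to 4.15, but a proportional gain of acetylation at all sites predicts the same. A SAHA response that differs between the populations stays open and untested, the difference being 0.078 with the common input.

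The aged vehicle neuronal library had less H4K12ac around the TSS than the young one. A larger share of evenly spread background reads as the whole cause is argued against by the shape of the profile only. The straight line of the aged on the young profile left residuals down to -5.62%, against -2.84% in the 4 fits without this library. The non-neuronal fits among these share libraries. Evenly spread background would also leave the peak width, taken midway between flank and maximum, unchanged, and would create no dip. The width was 956 bp in the young and 1084 bp in the aged library, and the dip none and 2.12%. Dips also differed among non-neuronal libraries (0.861% to 2.77%), and these measures are not independent of the residuals. The fixed point of the aged on the young profile was 5.49 (5.28 to 5.71 for a 1% change of scale), above the input flanks, but this does not set that fit apart. In the other fits it was 4.94 for age, 4.05 for SAHA and 6.04 for SAHA against young in non-neuronal nuclei. It was 3.25 for SAHA against young in neuronal nuclei. Non-neuronal nuclei mixed in stay open, though they would raise the level. A mixture of young neuronal and non-neuronal signal would lie between its sources. The aged signal of 10.2 lay below the young neuronal library, 11.9, and the lowest non-neuronal one, 12.2. The latter gap exceeded 3 SD of the non-neuronal libraries (1.93). Over its own flank the aged value, 1.99, was also below both, 2.31 and 2.14, but below the non-neuronal one by less than 3 SD (0.225). These SDs span 3 conditions and are not a spread of replicates, so they cannot settle it. The peak width of 1084 bp lay nearer the non-neuronal libraries (1131 to 1165 bp) than the other neuronal ones (956 and 922 bp). The upstream dip of 2.12% lay among the non-neuronal ones (0.861% to 2.77%), against 0.0639% in SAHA neuronal nuclei and none in young ones. The downstream maximum over that more than 200 bp upstream was 1.33, against 1.30 to 1.33 in non-neuronal and 1.41 and 1.44 in other neuronal libraries. These features all draw on the signal upstream of the TSS, so they are not separate signs. The rise upstream over that downstream went the other way. It was 0.591 ± 0.0034 (counting error), as in SAHA neuronal nuclei (0.591) and below all non-neuronal libraries (0.625 to 0.645). The young neuronal library, at 0.625, overlapped the non-neuronal ones, so this ratio did not fully separate the populations. A GC or amplification bias also stays open, as the inputs, which differed by a log2 of 0.13 in the opposite direction, were amplified separately. A link with the divisor or with duplicate reads was not tested and stays open, also for the neuronal SAHA difference. The smallest unit of signal was 2.74e-08 in the young, 1.85e-08 in the SAHA and 1.52e-08 in the aged vehicle neuronal library. Their signals fell in the same order, at 11.9, 11.4 and 10.2. In non-neuronal nuclei the SAHA library had the highest divisor, but the aged vehicle library the lowest signal. Age itself stays open too, untested without replicates.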

How the results depend on the processing

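The common input, the exchange of the 2 aged vehicle inputs and the share of the age difference were chosen after the data were seen, and the other alternatives before. A value counted as moved beyond the SD of the 6 inputs, a log2 of 0.078, or 5 percentage points for the share; inputs are not replicates, so this is only a scale. Of 64 alternative values of the age, SAHA and population differences, 35 stayed within it, 24 moved in the same direction and 5 reversed. These include the values with the common input, which nearly repeat those of ChIP alone. The aged SAHA against young differences stayed below 0 under the alternatives run, at -0.10 to -0.048 in neuronal and -0.15 to -0.062 in non-neuronal nuclei. For ChIP alone they were -0.061 and -0.062, nearer 0 than the SD of the inputs. The exchange cannot move these differences, since they use no aged vehicle library.

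ChIP over input stayed above 0 under all alternatives run, with p = 0.03125 in the exact permutation test over 6 pairs, and with 1 pair left out at 1.43 to 1.52 (exact p = 0.0625, the smallest for the remaining pairs, which says nothing of stability). ChIP alone can give no value for it, and a pseudocount does not apply to profiles. For ChIP alone, the log2 age difference was -0.22 in neuronal and -0.14 in non-neuronal nuclei, the SAHA difference 0.16 and 0.082 (reversed), and the differences between populations -0.078 for age and 0.079 for SAHA. With the common input these were -0.22, -0.14, 0.16, 0.082 (reversed), -0.078 and 0.078. A common input all but cancels in a ratio of libraries, so it nearly repeats ChIP alone and is no separate check. With the aged inputs exchanged they were -0.21, -0.17, 0.14, 0.044 (reversed), -0.041 and 0.092, and neuronal against non-neuronal nuclei gave -0.071. These alternatives differ from the main value in the input alone. With input subtracted, the age difference was -0.46 in neuronal and -0.16 in non-neuronal nuclei, the non-neuronal SAHA difference 0.028 (reversed) and neuronal against non-neuronal -0.31. With 1000 bp, the neuronal age difference was -0.27 and the differences between populations -0.24 for age and 0.28 for SAHA, the latter 0.47 with 200 bp. Divided by own flank, neuronal against non-neuronal reversed to 0.0055, to 0.096 at 3 months and to 0.15 with SAHA, and with 200 bp to 0.041 with SAHA. Leaving out 1 condition gave -0.24 to -0.049, the latter without the aged vehicle pair. The share of the age difference was 62.7% to 81.7% in neuronal nuclei, and 17.2% to 60.2% in non-neuronal nuclei apart from -420% divided by own input. Where no cause is named it was not tested. Counting error reached 0.158% of a window mean, a lower limit that leaves out differences between inputs, the unknown normalization and the missing replicates.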

Other observations

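The tests of explanations in this part were all chosen after the inputs had been seen, and the carry-over test was run with inputs pooled before it was run per input.

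The width of the H4K12ac peak, measured midway between flank and maximum, differed between the populations. In neuronal nuclei it was 956 bp at 3 months, 1084 bp at 20 months with vehicle and 922 bp with SAHA. In non-neuronal nuclei it was 1131, 1165 and 1163 bp. The downstream maximum was 1.41, 1.33 and 1.44 times the highest value more than 200 bp upstream in neuronal nuclei, and 1.33, 1.30 and 1.31 times in non-neuronal nuclei. These ratios depend on that search limit. In the young neuronal library the upstream value, 10.5, lay at the limit, and the signal was 11.9 in the last 10 bp before the TSS. At 1000 bp downstream the signal was 1.08 to 1.10 times that at 1000 bp upstream in the 6 ChIP libraries.

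For the rise of the inputs at the TSS, ChIP reads carried over into the input, as the only source, are argued against for the aged vehicle neuronal input, whose rise upstream was 0.823 ± 0.040 (counting error) of that downstream, and for the aged SAHA non-neuronal input, at 0.757 ± 0.026, since no ChIP library exceeded 0.645. The young non-neuronal input (0.765 ± 0.046) and the inputs with a small rise (lowest 0.675 ± 0.126) lay within 3 counting errors of that value and stay open. Easier fragmentation of open promoter chromatin could not be excluded, with rises up to 12.4% and accessibility not measured. An exchange of the 2 aged vehicle inputs between the populations may also account for the placement: exchanged, the lowest non-neuronal rise would be 8.68% and the highest neuronal one 3.44%. The flanks would separate likewise, at 4.09 against 4.04. The inputs with the 3 highest rises also had the highest flanks, so the flanks are no separate sign of an exchange. This hypothesis came from the same values, 6 of the 20 placements of the 3 highest rises lie 1 exchange within a condition from a split by population in either direction (3 with non-neuronal inputs the higher), and the labels were kept throughout, so it cannot be told apart from chance here.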
